A study of Arabidopsis thaliana with 12 samples.

How the data were processed

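The series holds 12 arrays of total RNA from Arabidopsis thaliana, 6 of wild type and 6 of the mutant mak3, and the only values used here are those of the deposited value table, with 1 intensity for each array and each of 3439 numbered probes. Genotype and array number were taken from the labels. The deposited intensities are linear and never negative, contain exact zeros, reach an upper limit of 100 on most arrays and have a mean near 1 on each array. How the authors scanned the arrays, corrected the background and scaled these deposited intensities is not given in the sources used here, so the scale and its centre stay unknown, and no background signal was at hand to judge whether a probe lay above it. In all, 53 probes were at 0 on all 12 arrays, 182 were at 0 on at least 1 array and 3 reached the upper limit on at least 1 array. The precision of every value is limited by the number of arrays.

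Probe names come from the platform annotation, updated through gene identifiers. Of the 3439 probes, 692 name 1 gene, 870 name several and 1877 are unnamed here. Only probes with 1 gene are named in the text, and 2 of these were missing from the gene table and kept their older symbol. The annotation is a limit of its own: in 92 sets of probes with identical annotation, 91 of them with several genes, the mak3 minus WT differences correlated at Spearman's rho = 0.151 across the sets and the mean log2 levels at 0.124 (Pearson's r = 0.0854). Names of probes with several genes are therefore uncertain, and these sets say little of probes with 1 gene. No coordinates are given because the files name no genome build. No probe naming MAK3 alone, or its neighbour At2g38140 alone, was at hand, so the planned check of the mutated gene's own transcript was not analysed here and the group labels have no such check.

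The medians of the arrays differed by 44.1%, above the limit of 10% set before the data were examined. The arrays were therefore quantile-normalized with limma 3.58.1 in R 4.3.3. The deposited mak3 medians were below those of WT in pair 3-4 (0.490 and 0.492 against 0.564 and 0.559). They were also below in pair 5-6 (0.420 and 0.421 against 0.605 and 0.605). In pair 1-2 they were slightly above (0.598 and 0.599 against 0.579 and 0.585). Quantile normalization takes such differences off, whatever their origin. Values under the 1st percentile of all positive values (0.0396, or -4.66 on the log2 scale) were then set to it, which affected 166 probes of each array, and log2 was taken. The design foresaw that repeat readings of 1 sample would be averaged. Arrays 1 and 2, 3 and 4, and 5 and 6 of a genotype deviated together from their genotype mean (r = 0.757 to 0.883 within such a pair, at most -0.0641 for arrays of the same genotype with other numbers), so they were averaged before the test, which leaves 3 samples for each genotype. The sampling noise of an intensity cannot be computed, so this rests on the correlations alone.

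Each probe was tested with limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The SE printed is the moderated SE of limma. The pair numbers were checked for pairing: the WT and mak3 samples with the same number deviated together from their genotype means, at r = 0.601, 0.556 and 0.738 across probes, so the numbers pair the samples, as judged from the data. The fit without the pair number was the planned one, and the fit with it as a block is given where it changes a call. The printed SE is from the fit without it, so it holds spread between pairs that cancels in a paired difference. With the block the SE was 0.10 in place of 0.38 for AT3G13120 and 0.11 in place of 0.36 for CRR21. It was not smaller for every gene, with 0.16 in place of 0.14 for AT1G31790. Gene lists with at least 5 probes were tested with camera of limma at a preset correlation of 0.01, with an estimated correlation and with fry beside it, adjusted over the 6 lists tested. Of 23 lists fixed before the data were examined, 1 had 5 or more probes, 7 had 1 to 4 and the other 15 were not analysed here. The 5 other tested lists were drawn up after some of the values had been seen, and 1 of them joins the fixed photosynthesis lists. Probes naming several genes were counted in a list only if all their genes belong to it.

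The rule for named genes, fixed before the data were examined, took the genes with the largest changes among those past the threshold. Since none passed, it took the 5 with the smallest p in each direction, and for each tested list the 2 members with the smallest p. Other genes named in the text were chosen after their values were seen. On simulated data with the size and spread of these arrays, the test of mak3 against WT over 3439 probes found 20% of 100 probes changed 2-fold and 64% of 100 changed 4-fold, with 6 false calls. With the pair number as a block it found 41% and 80%, with 11 false calls. The simulated noise was independent between probes and samples, and the simulation for the fit without the block held no pair effect. The real samples pair by number and neighbouring probes differed alike, so these shares and false calls need not hold for the real arrays.

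Alternatives listed in advance were other scalings (values as deposited, median scaling, cyclic loess), an offset of 0.143 before log2, a filter on dim probes, blocks, array weights, other variance models and tests, and leaving out each array. Added after seeing the data were the 12 arrays as separate samples, leaving out each pair, leaving out arrays 1 and 2 of both genotypes, and removal of the positional pattern. The last was done in 2 ways, by taking off from each array the running median of 24 neighbouring probes or the grid median, which is the median over 34 probes up to 3 numbers and up to 2 steps of 288 numbers away. The step of 288 is the distance at which the differences of pair 3-4 correlated most over a range of distances well beyond neighbours. "The median of neighbouring probes" in the results stands for the grid median. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.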

Results

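Gene expression in the Arabidopsis thaliana mutant mak3 was compared with that of wild-type (WT) plants of the Columbia ecotype. Per the labels the mutant is impaired in an N-acetyltransferase of the cytoplasm, and the comparison asks which transcripts differ when this enzyme is impaired. MAK3 (At2g38130) encodes the catalytic subunit of the N-terminal acetyltransferase C, an enzyme that adds an acetyl group to the first residue of many proteins. Total RNA was read on 12 arrays, 6 for each genotype, and each array gave 1 intensity for each of 3439 probes. The mean intensity of an array lay between 0.946 and 1.05, its median between 0.420 and 0.605, and between 129 and 142 probes of an array were at 0. The tissue and the growth conditions are not given in the sources used here, and the MAK3 transcript was not analysed here.

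The 6 arrays of a genotype were counted as 3 samples. Arrays numbered 1 and 2, 3 and 4, and 5 and 6 within a genotype correlated at r = 0.976 to 0.994 across probes on the log2 scale, against 0.842 to 0.941 for arrays of the same genotype with other numbers. Each such pair was close to a repeat reading of 1 sample, so its mean was used and n = 3 for each genotype. Nothing in the labels says whether these samples came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

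The 10 genes with the smallest p values in mak3 against WT had differences of the same sign in all 3 pairs, but none of them passed the test. The choice by smallest p favours such agreement, so it is no separate evidence. Over all probes 36.5% had one direction in all 3 pairs. The lowest of these 10 were AT3G13150, a pentatricopeptide repeat protein (a family of organelle RNA-binding proteins), with a mak3 minus WT difference of -0.73 ± 0.13 on the log2 scale (SE, n = 3 against 3), and AT2G38500 at -0.61 ± 0.15. AT2G39670, of the radical SAM superfamily, was at -0.50 ± 0.11, AT2G26110 at -0.40 ± 0.08, and AT2G25870, a YbeY-type endoribonuclease of the chloroplast, at -0.39 ± 0.09. The highest of the 10 were AT3G04210, which encodes a protein of the TIR-NBS disease-resistance family, at 0.94 ± 0.26, AT1G49850 at 0.75 ± 0.26, and AT3G25840, a protein kinase of the splicing-related PRP4 type, at 0.69 ± 0.17. The protein kinase gene ATSIK (AT3G08760) was at 0.35 ± 0.10 and DEMETER (DME, AT5G04560), a DNA glycosylase that removes methylated cytosine, at 0.23 ± 0.08. The difference of DME was 0.00 with the values as deposited, where the median of all probes was -0.19, and 0.07 after the median of neighbouring probes was taken off. With the arrays scaled to a common median AT3G13150 was at -0.37, AT2G26110 at -0.23 and ATSIK at 0.57. With the values as deposited AT2G25870 was at -0.61 and AT3G25840 at 0.46, and with array weights AT1G49850 was at 0.46.

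**Figure D1:**
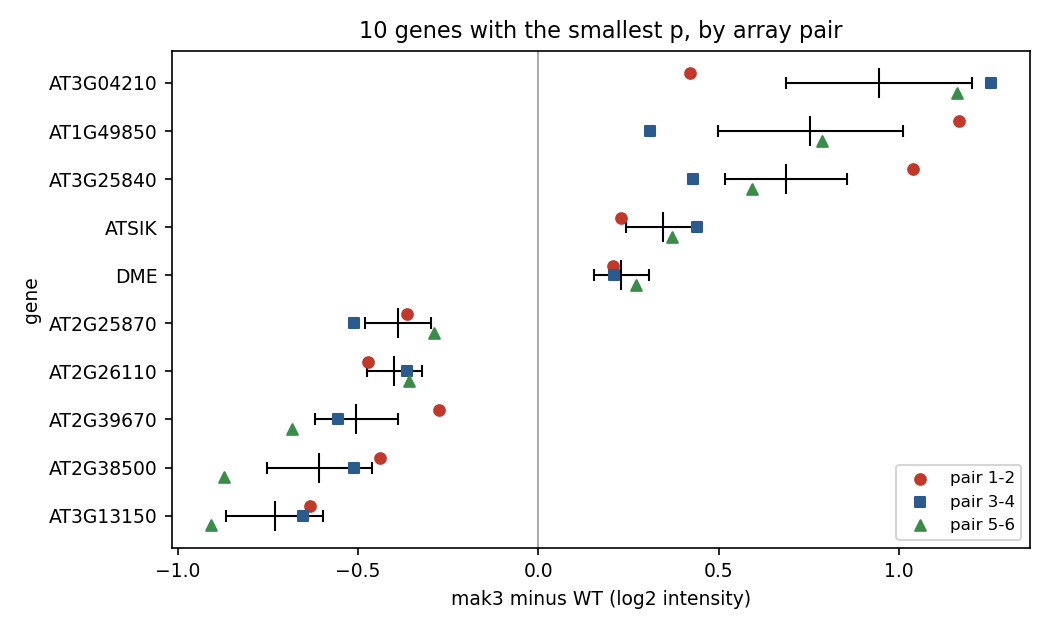
Mak3 minus WT difference (log2 intensity, horizontal axis) of the 10 genes with the smallest p, 5 in each direction. Symbols are the 3 array pairs and the bar is the mean with its limma SE from the fit without the pair number (n = 3 against 3). All 3 pairs of each gene lie on the same side of 0, from -0.73 for AT3G13150 to 0.94 for AT3G04210 in the mean. The choice by smallest p favours this.

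With limma, 0 of 3439 probes were higher and 0 lower in mak3 at an adjusted p under 0.05, and the smallest adjusted p was 1. At an unadjusted p under 0.05 there were 134 probes, 61 higher and 73 lower. With no difference and independent samples, 172 would be expected. The samples pair by number, which this fit leaves out, so 134 cannot be read as fewer than chance gives. With the pair number as a block, limma again called 0 probes (smallest adjusted p = 0.354). That fit gave 458 probes at an unadjusted p under 0.05, above the same 172. Neighbouring probes differed alike, so this excess is no test of a difference. When the 12 arrays were taken as separate samples, which counts each sample 2 times and makes p too small, limma called 10 probes higher and 14 lower, and 7 of these 24 name 1 gene: AT3G04210, AT3G25840, AT3G13150, AT2G38500, AT2G39670, AT2G26110 and AT2G25870. An exact test of 3 samples against 3 cannot reach a p below 0.1.

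Genes of photosynthesis gave no call. Of 9 probes for the light-harvesting antenna, both photosystems, electron transport and the Calvin cycle, 0 passed in limma and 0 had an unadjusted p under 0.05, with 3 higher, 6 lower and a median difference of -0.07 (camera adjusted p = 0.382). PSAN (AT5G64040), the N subunit of photosystem I, was at -0.42 ± 0.19, and LHB1B2 (AT2G34420), a chlorophyll-binding protein of the photosystem II antenna, at -0.36 ± 0.18 (SE, n = 3 against 3). PSB27, PSBY and PSBW of photosystem II were at 0.36, 0.10 and -0.07, and the Calvin cycle enzymes sedoheptulose bisphosphatase (SBPASE) and phosphoribulokinase (PRK) at -0.09 and 0.03. When the arrays were scaled to a common median, the median of these probes was 0.10, PSAN was at -0.05 and LHB1B2 at -0.02, so the median has no settled sign and the differences of both genes no settled size.

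Among plastid ribosomal proteins, the only list fixed before the data were examined that had 5 or more probes, 4 of 6 probes were higher, 1 was lower and AT5G65220 was at 0 on every array. Its median difference was 0.06 (camera adjusted p = 0.868) and 0 members passed, also when adjusted over the list alone. The 2 members with the smallest p were AT3G54210, a protein of the large subunit, at -0.22 ± 0.12 and AT3G13120, of the small subunit, at 0.22 ± 0.38 (SE, n = 3 against 3). Over 36 alternatives AT3G54210 went from -0.35 to -0.11. AT3G13120 was at 0.00 and the median at -0.17 with the values as deposited, where the median of all probes was -0.19. Tetrapyrrole biosynthesis had 3 probes, among them CHLM at 0.01 and AT1G74470, geranylgeranyl reductase, at -0.13, with 0 members passing when adjusted over the list alone. Antioxidant enzymes had 3 probes with a median of -0.13, the peroxiredoxin gene AT3G52960 at 0.27 and 2 probes that name several genes at -0.50 and -0.13. Adjusted over this list alone, 0 of the 3 passed in the planned fit, and with the pair number as a block 1 did, the probe at -0.50. The probe at -0.13 names the same genes (TAPX and SAPX) and had an unadjusted p of 0.224 in limma with that block.

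Of 11 probes for thylakoid biogenesis and the NDH complex, 4 were higher and 6 lower, with a median difference of -0.02 (camera adjusted p = 0.734). NdhS (AT4G23890), a subunit of the chloroplast NADH dehydrogenase-like complex, was at 0.41 ± 0.30, with 1.13 in pair 1-2 and -0.09 in pair 5-6, and went from 0.05 to 0.66 over 36 alternatives (0.66 with median scaling, 0.20 with array weights). CRR21 (AT5G55740), a pentatricopeptide repeat protein needed for editing of the plastid ndhD transcript, was at 0.33 ± 0.36 (SE, n = 3 against 3). Of 12 probes for pentatricopeptide repeat proteins, 11 were higher and AT3G13150 alone was lower, with a median of 0.16 (camera adjusted p = 0.353), and AT3G13150 was the 1 member that passed when adjusted over the list alone. AT1G31790 of this family was at 0.35 ± 0.14. With the values as deposited, 7 of the 12 were higher, the median was 0.02, CRR21 was at 0.13 and AT1G31790 at 0.15, but the median of all probes was -0.19 there, and relative to it the list was at 0.20. This list was written after AT3G13150 had been seen, so that pass is not independent evidence.

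Reproductive development had 6 probes, 4 higher and 2 lower, with a median difference of 0.18 (camera adjusted p = 0.148). DME was at 0.23 ± 0.08 and SAP (STERILE APETALA, AT5G35770), a gene of flower development, at 0.31 ± 0.21 (SE, n = 3 against 3). The fry test of limma gave an adjusted p of 0.459 and, with the pair number as a block, of 0.0434, while camera with that block gave 0.132. With an estimated correlation camera gave 0.485 and, with the block, 0.481. With the values as deposited the median was -0.03 and SAP was at 0.05, and relative to the median of all probes there, -0.19, the list was at 0.15.

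The genes of glycosyl hydrolase family 9, which encode endoglucanases that act on cell-wall glucans, were the 1 group to pass the preset test. All 10 probes were lower in mak3 on average (9 of 10 with cyclic loess scaling), with a median difference of -0.23, and camera gave an adjusted p = 0.0367 (0.0458 with the pair number as a block). The call was lost with an estimated correlation (adjusted p = 0.485) and with fry (adjusted p = 0.459). After the median of neighbouring probes was taken off it was lost too, with the list median at -0.12 (camera adjusted p = 0.360). With the running median taken off instead, the call was kept (list median -0.23, camera adjusted p = 0.0182). It was lost with little change of the list median with cyclic loess (-0.21, adjusted p = 0.0742) and without the dimmest probes (-0.23, adjusted p = 0.192). With the values as deposited it was lost as well (adjusted p = 0.0663), at a list median of -0.46, or -0.27 relative to all probes. It was also lost without WT array 1, mak3 array 2 or WT array 3, at adjusted p = 0.120, 0.153 and 0.0536 in camera. GH9B11 (AT2G44560) was at -0.19 ± 0.08 and GH9B16 (AT4G38990) at -0.33 ± 0.23 (SE, n = 3 against 3), with -0.40 and -0.55 as deposited and -0.09 and -0.13 after the median of neighbouring probes was taken off, and 0 members passed in limma over all probes or over the list alone. By pair the list median was 0.02 in pair 1-2, -0.29 in pair 3-4 and -0.25 in pair 5-6. The list was drawn up after the data had been looked at, and several of its probes name overlapping sets of genes.

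Probe by probe, the mak3 minus WT differences of pair 1-2 had almost no correlation with those of the other pairs. The running medians of pair 1-2 went weakly the opposite way (Spearman's rho -0.192 with pair 3-4 and -0.243 with pair 5-6). Across the 3439 probes, which are not independent replicates, Pearson's r was 0.00526 between pairs 1-2 and 3-4, 0.0283 between pairs 1-2 and 5-6, and 0.629 between pairs 3-4 and 5-6 (Spearman's rho -0.0303, -0.0158 and 0.726). The SD of the differences was of similar size in the 3 pairs, at 0.46, 0.39 and 0.45 on the log2 scale. One direction in all 3 pairs was seen for 36.5% of the probes, 561 higher and 694 lower. The 74.1% with one direction in pairs 3-4 and 5-6 would give 35.6% if pair 1-2 were unrelated to both, so this share shows little beyond the relation of those 2 pairs.

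**Figure D2:**
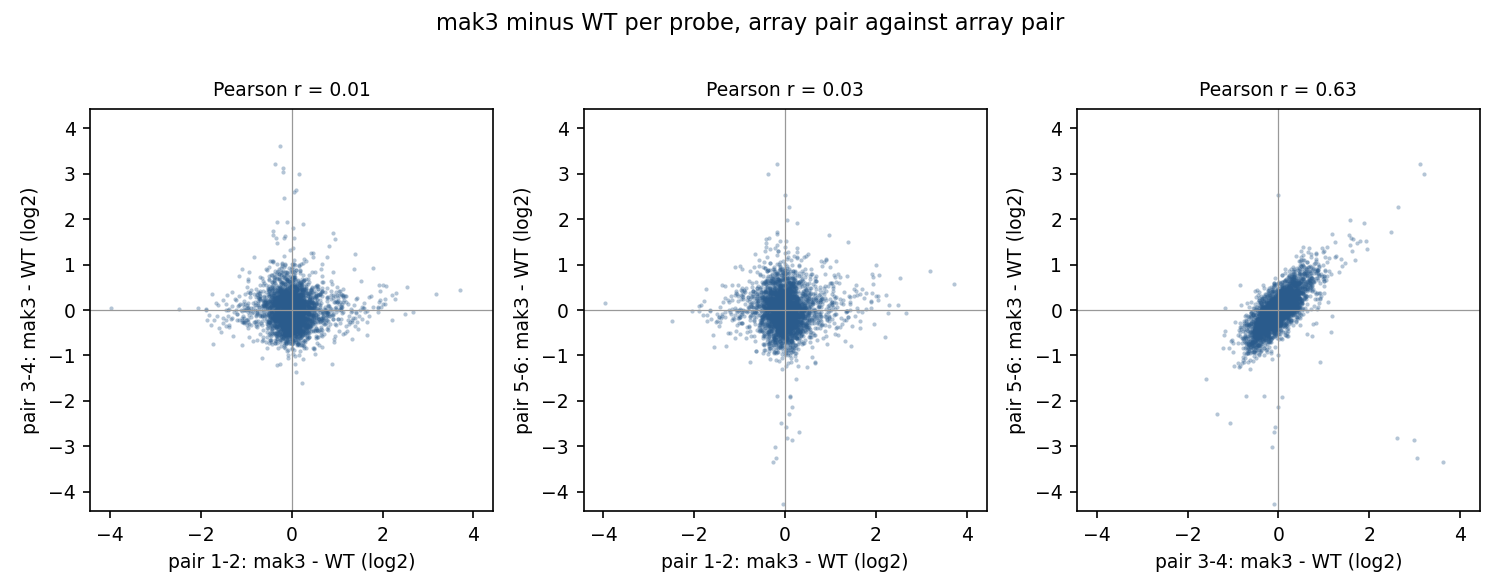
Mak3 minus WT difference (log2 intensity) of each of 3439 probes in 1 array pair against another, 1 point per probe. The points of pairs 3-4 and 5-6 lie along the diagonal (Pearson r = 0.63), and those of pair 1-2 against either other pair do not (r = 0.01 and 0.03).

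Probes with neighbouring numbers differed alike. In pairs 1-2, 3-4 and 5-6, the differences of probes 1 number apart correlated at Spearman's rho = 0.140, 0.443 and 0.376, and those of probes 288 numbers apart at 0.160, 0.392 and 0.314. The same held between samples of 1 genotype, where the differences of probes 1 number apart correlated at 0.149 to 0.509. The highest value was that of WT between pair 1-2 and pair 3-4, and the lowest that of mak3 between pair 3-4 and pair 5-6. AT2G39670 and AT3G13150 both lie in stretches of low running medians in pairs 3-4 and 5-6. After the median of neighbouring probes was taken off, AT2G39670 was at -0.28, AT2G38500 at -0.38, AT3G13150 at -0.72 and AT3G25840 at 0.58, and with the running median taken off instead they were at -0.22, -0.43, -0.51 and 0.53. AT2G26110 went the other way, to -0.43 and -0.68.

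**Figure D3:**
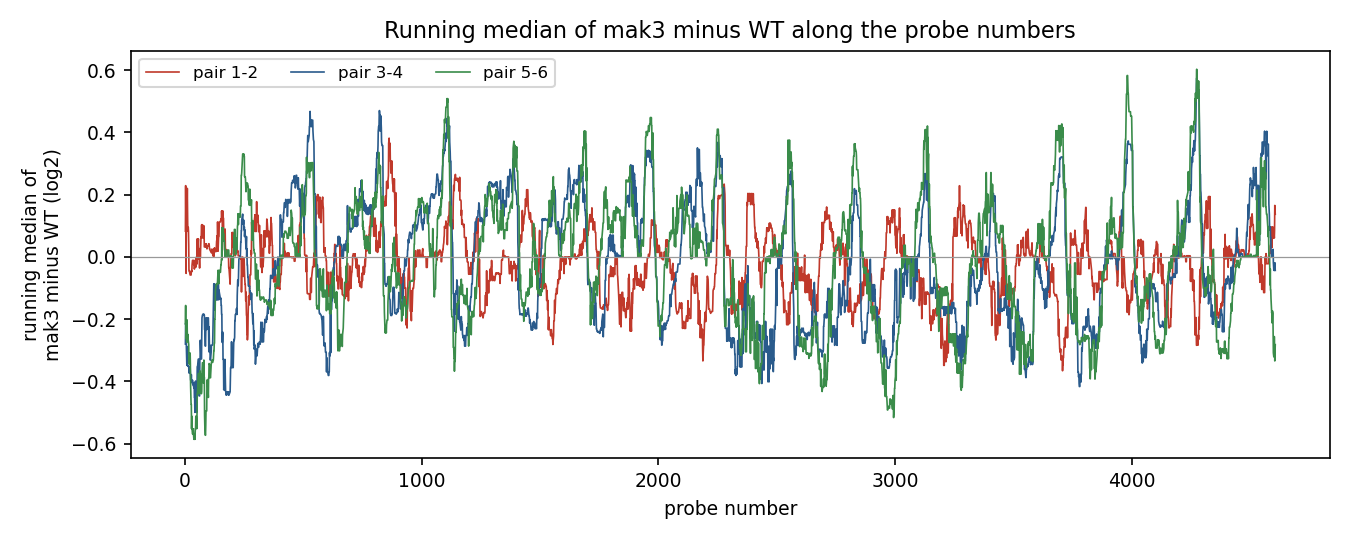
Running median over 24 neighbouring probes of the mak3 minus WT difference (log2 intensity, vertical axis) along the probe number (horizontal axis), 1 line for each array pair. The lines of pairs 3-4 and 5-6 move together and repeat every 288 numbers (Spearman's rho of the lines 0.774), between -0.50 and 0.57 and between -0.59 and 0.60. The line of pair 1-2 correlated at -0.192 with that of pair 3-4 and at -0.243 with that of pair 5-6.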

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

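One group of arrays held a value set apart from the rest. For ATSIK in mak3, array 1 was at 0.92 on the log2 scale and the nearest of the other 5 arrays at 0.75, a gap of 0.659 of the whole range, which is above the 95% critical value of Dixon's test for 6 values. Among 40 groups of 6 arrays examined (20 genes in 2 genotypes) this was the only 1, and chance alone sets apart about 1 group in 20 when the 6 values are independent, which repeat readings of 3 samples are not, so this rate does not hold exactly here. No explanation was tested for it.

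The tests of swapped labels, of an effect common to all pairs, of the spotting layout and of the mutation as the origin of the positional pattern were chosen after the result was seen. The differences of pairs 3-4 and 5-6 went together and those of pair 1-2 with neither. If all 3 pairs shared an effect, an exchange of the group labels in pair 1-2 would make its correlations with the other pairs negative. The lower Pearson's r was 0.00526, so an exchange does not account for the lack of a relation. An exchange only turns the sign, so values near 0 cannot tell whether it took place. At an unadjusted p under 0.05 limma gave 134 probes with the real labels and 133 with those of pair 1-2 exchanged. The covariance between pairs 3-4 and 5-6 was 0.112. If it came from the mutation alone, an effect of like size in all 3 pairs would need a covariance with pair 1-2 near it. If part of it has another origin, a smaller covariance would do, and a small common effect is not excluded. The upper 95% bound of the covariance with pair 1-2 was 0.0135 over blocks of 24 probes. It was 0.0129 over groups of 24 neighbouring places in the repeat of 288 probe numbers, with all repeats of a place kept together. Both bounds measure the spread over probes, not over samples, and pair 1-2 holds 1 sample of each genotype. They show how small the covariance was in these pairs, but they cannot limit a mutant effect over samples. The covariance is also the quantity that showed the pattern, so it is no separate test of such an effect. A trend along the probe numbers was not the whole origin either, since the Spearman correlation of pairs 3-4 and 5-6 was 0.617 after the running median was taken off and 0.631 after the grid median was. It stays open, and was not tested, whether pairs 3-4 and 5-6 shared plants, RNA or membranes that pair 1-2 did not, or whether the mutant differed from WT in another way in the material of pair 1-2, and both may hold. Before normalization, the median intensity was lower in mak3 than in WT in pairs 3-4 and 5-6 but not in pair 1-2. Whether this bears on the pattern was not tested.

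The second pattern was that probes with neighbouring numbers differed alike. Genes that neighbour each other in the genome do not account for it in pairs 3-4 and 5-6. Probes up to 6 numbers apart whose genes lie on different chromosomes correlated there at 0.475 and 0.446. In pair 1-2 such probes correlated at 0.0511, against 0.177 for genes on the same chromosome. For pair 1-2 this explanation is therefore not excluded. The mutation is not needed for neighbouring probes to differ alike. In the 6 differences between samples of 1 genotype, probes 1 number apart also correlated, at a median of 0.260 (0.149 to 0.509). This cannot exclude a part tied to the genotype in pairs 3-4 and 5-6. Their values were 0.443 and 0.376, and their running medians went together (Spearman's rho 0.774). A spotting layout that repeats at a fixed step of probe numbers is a candidate explanation: the step of 288 found in pair 3-4 gave 0.314 in pair 5-6, against -0.140 for probes 144 numbers apart in the same pair. The grid median took 14.7% of the variance of the differences in each of pairs 3-4 and 5-6 and none in pair 1-2 (-3.33%), and the position of the probes on the arrays was not at hand to test the layout directly.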

How the results depend on the processing

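Of 40 alternatives, 34 tested each probe on pair means, and all 34 gave 0 probes higher and 0 lower in mak3 (limma, or the exact rank-sum test in 1 of them), including the replicate block and every fit that leaves out an array or a pair. The smallest adjusted p of limma among them was 0.0530, with array weights, whose estimation did not fully converge. The arrays of a pair as a random block also gave 0. Leaving out pairs, taking off the grid median and the settings that follow were added after seeing the data. Calls were made with arrays used singly: 10 higher and 14 lower with 12 separate samples, 170 and 243 with the replicate block besides, and 40 and 34 with the pair number as a block and the arrays of a pair as a random block. Their construction counts more samples or ties them by a correlation averaged over probes. The count of lists past the threshold, 1, became 0 with values as deposited, cyclic loess, without the dimmest probes, 12 arrays with or without the block, the grid median taken off with or without the block, an estimated correlation and fry, and it ranged from 0 to 1 when an array or pair was left out. It was 0 without WT array 1, mak3 array 2 or WT array 3 (smallest camera adjusted p = 0.120, 0.153 and 0.0536), without WT pair 3-4 or 5-6 (0.403 and 0.267) and without mak3 pair 1-2, 3-4 or 5-6 (0.221, 0.0533 and 0.0559), and the cause was not tested. On the pair means the replicate block changed no call of camera or of limma over all probes, and 1 antioxidant probe passed over its list alone with it. With fry it changed the call of reproductive development (adjusted p = 0.459 without the block and 0.0434 with it). Of the values of named genes, 691 kept their direction and side of the threshold, 24 newly passed, all with arrays used singly, and 4 changed sign. Of the list medians, 166 kept both, 23 changed sign or reached 0 without a call and 15 lost the call. Lists were not run with the arrays of a pair as a random block. With no background signal, no probe could be judged against it.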

Other observations

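Some probes differed by over 1.5-fold in the same direction in all 3 pairs, 10 higher and 6 lower in mak3, though none passed in limma over all probes (smallest adjusted p = 1, 134 probes at an unadjusted p under 0.05). Only 2 of the 16 name 1 gene, AT3G13150 with -0.63, -0.65 and -0.91 in pairs 1-2, 3-4 and 5-6, and AT5G38360, lower in all 3 but near the lowest values of the arrays, so that its differences have no firm size. The probe with the largest mean difference among them, number 289, is unnamed here and stood at 1.39 ± 0.16 on the log2 scale (SE, n = 3 against 3), with 0.96, 1.56 and 1.64 in the 3 pairs. It was dim as well, with a WT mean of -2.98 and a mean signal at percentile 11.3 of all probes. Probe number 4262, also unnamed, stood at 0.95 ± 0.14, with 0.91, 0.83 and 1.11. These probes were chosen after their values were seen.

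Other splits of the 6 samples into 3 and 3 were compared with the real one, in a test of the unadjusted counts chosen after the result was seen. The 10 possible splits are too few for a share under 0.05. The real split gave 134 probes at an unadjusted p under 0.05, 6 of the 10 splits gave as many, the real one included, and the highest other count was 785, in a split that set both samples of pair 1-2 with mak3 pair 3-4 against the rest. The high counts come from splits that follow the pair numbers, which points to a structure of the samples. Among the 4 splits that part the members of every pair, the real one gave 134 and the highest other 133. For the gene lists, the real split gave the smallest camera p, 0.00612, in 1 of 10 splits, and the smallest of the others was 0.00943. The 0.00612 is that of glycosyl hydrolase family 9, a list drawn up after the data had been looked at. That may favour the real split, so its rank is no independent evidence. With the 12 arrays as separate samples, 3 of 100 drawn splits, the real one included, gave at least the real 24 probes and the highest other gave 731, but all 3 keep repeat readings together and splits that break them up are not comparable. Of the 10 splits that keep them together, 6 gave as many probes, the real one included, and the highest other gave 1276, in a test chosen after the result was seen.

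The probes of glycosyl hydrolase family 9 lie close together in the repeat of 288 numbers. Counted within that repeat, 9 of the 10 lie between place 268 and place 62 of the next repeat, and the grid medians of 8 of these 9 were below 0, from -0.22 to -0.02. The other was at 0.09, and its probe moved from -0.31 to -0.40 when it was taken off. That the positional pattern accounts for the low values is a hypothesis formed after they were seen. Taking off the grid median, an alternative chosen after seeing the data, left a list median of -0.12 from -0.23, with a camera adjusted p of 0.360 (0.00838 to 0.403 over the alternatives run with camera at the preset correlation), and 9 of the 10 probes were still lower. Taking off the running median, also chosen after seeing the data, left -0.23 with a camera adjusted p of 0.0182. Part of the difference may therefore be positional, and what the grid median left does not pass the test.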
